A study of Mus musculus with 24 samples.

How the data were processed

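RNA was extracted with Trizol from cerebella of male C57BL/6J mice aged 7 and 79 weeks and made into libraries with the Universal Plus mRNA-Seq kit, per the labels. The 2 libraries at each age were compared, and the 20 genomic samples of the 24 in the series were not analysed here. The deposited values are raw read counts per Ensembl gene, which the authors made by trimming reads with cutadapt, aligning them with STAR to the mouse genome build mm9 and counting them with HTSeq, per the labels, which give no versions. The annotation release and the strand setting of the counting are not given in the sources used here.

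Each count file ended in HTSeq summary lines, which were taken off before any total was computed. The libraries held 16367656 and 21124608 gene counts at 7 weeks and 18901921 and 22826993 at 79 weeks, over 19626, 20226, 20656 and 20786 genes with a count. The upper limit that a count of 0 allows was 3 counts of the library's total, and limits and intervals cover counting error only. Reads aligned to more than 1 place were 8.02% to 8.25% of each library and were not counted. Of 37991 gene identifiers, 32919 had a symbol. The 5072 without a symbol held 1.09% of the gene counts and were tested but not named, and 3 symbols were shared by more than 1 identifier. All 37 mitochondrial genes had 0 reads in each library. Whether the mitochondrial genome was part of the alignment is not given, so these zeros are not read as absence of expression and the limit for a count of 0 does not cover them.

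Analyses ran in R 4.3.3. Genes were kept by filterByExpr in edgeR 4.0.16 (minimum count 10, minimum total 15), which left 15292. Counts were scaled by TMM, with factors from 0.9812 to 1.023. The ages were compared by edgeR's quasi-likelihood F test with default settings and no covariates, as 79 minus 7 weeks, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The biological coefficient of variation was 9.43%. Levels are CPM, TMM-scaled read counts relative to library size, given as mean ± SD over 2 libraries, and log2 fold changes carry a standard error from the fit. A pseudocount of 0.5 CPM was used for log2 levels per library.

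In total 34 gene lists holding 751 genes were fixed before the data were examined, as were the tests, the rule for naming genes and the alternatives, apart from those given below as added. Of the 751 genes, 743 were found. The lists covered DNA methylation and demethylation machinery, complement and antigen presentation, interferon-stimulated genes, activated microglia, reactive astrocyte genes, immediate early genes, circadian clock genes, heat shock proteins and chaperones, nuclear-encoded oxidative phosphorylation, mitochondrially encoded proteins, cytosolic ribosomal proteins, synaptic receptors and vesicle proteins, collagens and matrix proteins, cell cycle, immature neuron and axon growth, cholesterol synthesis, cell senescence and clustered protocadherins beta. Marker lists covered granule neurons, Purkinje cells, inhibitory interneurons, unipolar brush cells, Bergmann glia and astrocytes, myelinating oligodendrocytes, oligodendrocyte precursors, microglia, endothelial cells and pericytes, choroid plexus, meninges and fibroblasts, brainstem and midbrain neurons, ependymal cells, red blood cells, lymphocytes and plasma cells, and perivascular macrophages and infiltrating myeloid cells. Lists with at least 5 tested members, 31 of the 34, were tested against all other genes by camera in limma 3.58.1 with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over lists. Camera with an estimated correlation and fry were run beside it. Between lists, 5 genes were shared.

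Genes named were the 10 largest rises and 10 largest falls among called genes with a mean of at least 1 CPM and no overlap between ages, the 5 smallest p-values, up to 4 called members of each list by smallest adjusted p or, where none was called, the 2 most abundant, and the genes Dnmt1, Dnmt3a, Dnmt3b, Tet1, Tet2 and Tet3. Some genes that this rule picks are not reported here. Calb2 and E2f1 were named outside this rule, after their values were seen.

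Alternatives were RLE, upper-quartile and library-size scaling, scaling without mitochondrial and the 10 most abundant genes, no low-count filter, a filter of 1 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, edgeR with legacy=FALSE or robust=TRUE, the replicate number as a block, and each library left out in turn. Leaving out a library leaves 1 at its age, which is then assumed to vary like the others. The low-count filter was then run anew and kept 15757 to 16175 genes, so the tested members of a list can differ. A crossed block and leaving out each library in DESeq2 were added after the data were seen. Differences between the medians of lists were tested by two-sided permutation of genes between lists (100000 permutations). For dilution of neurons, the difference also had to exceed a limit set after it was seen, first the median absolute deviation of the interneuron markers, which each difference passed, and then their SD, which was kept. The choroid plexus markers that failed the low-count filter were compared between libraries, a test added after the tested markers and the list without the filter were seen.

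The tests were also run on simulated data. With all 4 libraries, 59.7%, 91% and 100% of genes changed by 1.5-fold, 2-fold and 4-fold were called. There were 20 false calls among 15122 genes tested. The fitted direction, a separate measure over changed genes called or not, was right for 100% at each fold. Without 7-week replicate 1 the shares were 32.8%, 76.1% and 98.5%, with 5 false calls, and without 79-week replicate 1 they were 65.7%, 89.6% and 100%, with 55 false calls among 15215 genes. A simulated list of 20 genes shifted by 0.3 log2 units was called by camera with the preset correlation (adjusted p = 5.03e-19) but not with an estimated one (adjusted p = 0.297), and 0 of 30 unchanged lists were called by either. Simulated genes varied independently, with the same dispersion at both ages. These lists therefore cannot show false calls from genes that vary together.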

Results

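Cerebella of male C57BL/6J mice, an inbred laboratory strain, were profiled by mRNA sequencing at 7 and 79 weeks of age, with 2 libraries per age. The series holds 24 samples, and its 20 genomic samples, which measure cytosine methylation and hydroxymethylation in cerebellum and cortex, were not analysed here. The libraries held 16367656 and 21124608 gene counts at 7 weeks and 18901921 and 22826993 at 79 weeks. A gene with 0 reads could have reached up to 0.183 and 0.142 CPM (read counts scaled to library size) in the 7-week libraries and 0.159 and 0.131 CPM in the 79-week libraries, a limit that covers counting error only and not the mitochondrial genes. Of 37991 gene identifiers, 15292 passed the low-count filter and were tested. The labels do not say that the libraries of an age came from separate mice, so the p-values measure the spread between these libraries, which may be technical. Genes named are those chosen by rules fixed before the data were examined, unless stated otherwise.

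The comparison between ages asked how gene expression in the cerebellum differs between young adult and aged mice. Among gene lists, camera with a preset correlation called those of complement and antigen presentation, interferon, microglia, immediate early genes and ribosomal proteins higher at 79 weeks. It called those of granule neurons, Purkinje cells, oligodendrocytes, synapses and matrix lower. With an estimated correlation 0 lists were called (smallest adjusted p = 0.421). That test also missed a simulated shift (adjusted p = 0.297), but of only 0.3 log2 units in genes that varied independently. Estimated correlations were 0.771 for interferon, 0.679 for myelinating oligodendrocytes and 0.61 for immediate early genes, against the preset 0.01. Those for activated microglia and Purkinje cells were -0.0411 and -0.0225. The preset p-values are thus too small where members vary together, and neither test decides whether the lists changed. In each of the lists named here most members were not called singly. The kinase gene Ptk2b (ENSMUSG00000059456) rose from 2.95 ± 0.12 to 20.02 ± 0.41 CPM (mean ± SD, n = 2 per age), a 6.75-fold rise, and the membrane glycoprotein gene Tpbg (ENSMUSG00000035274) rose 5.66-fold. Gpr17 (ENSMUSG00000052229), a receptor of immature oligodendrocytes, fell from 31.3 ± 2.10 to 8.40 ± 0.57 CPM.

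In edgeR's quasi-likelihood test, 1352 genes passed an adjusted p of 0.05, 637 higher and 715 lower at 79 weeks, so 47.1% of the calls were higher. Scaling by library size alone gave 901 higher and 484 lower, or 65.1% higher. Of the called genes, 173 rose and 42 fell by at least 2-fold. All 1352 had ages that did not overlap, as did 57.7% of the genes tested, against 33.3% expected by chance for 2 against 2 libraries. The count changed with each library left out. Without 7-week replicate 1, edgeR called 0 genes (2610 at an unadjusted p under 0.05, and 243 called by DESeq2), and without 7-week replicate 2 it called 175. Without 79-week replicate 1 the count was 1579, and without 79-week replicate 2 it was 2425. DESeq2 called 1268 genes with all libraries, 430 without 7-week replicate 2, 382 without 79-week replicate 1 and 656 without 79-week replicate 2. Of the 93 genes reported by the naming rule that were called, 0, 24, 88 and 89 stayed called without 7-week replicate 1, 7-week replicate 2, 79-week replicate 1 and 79-week replicate 2, and all 93 kept their direction in each of these fits.

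**Figure D1:**
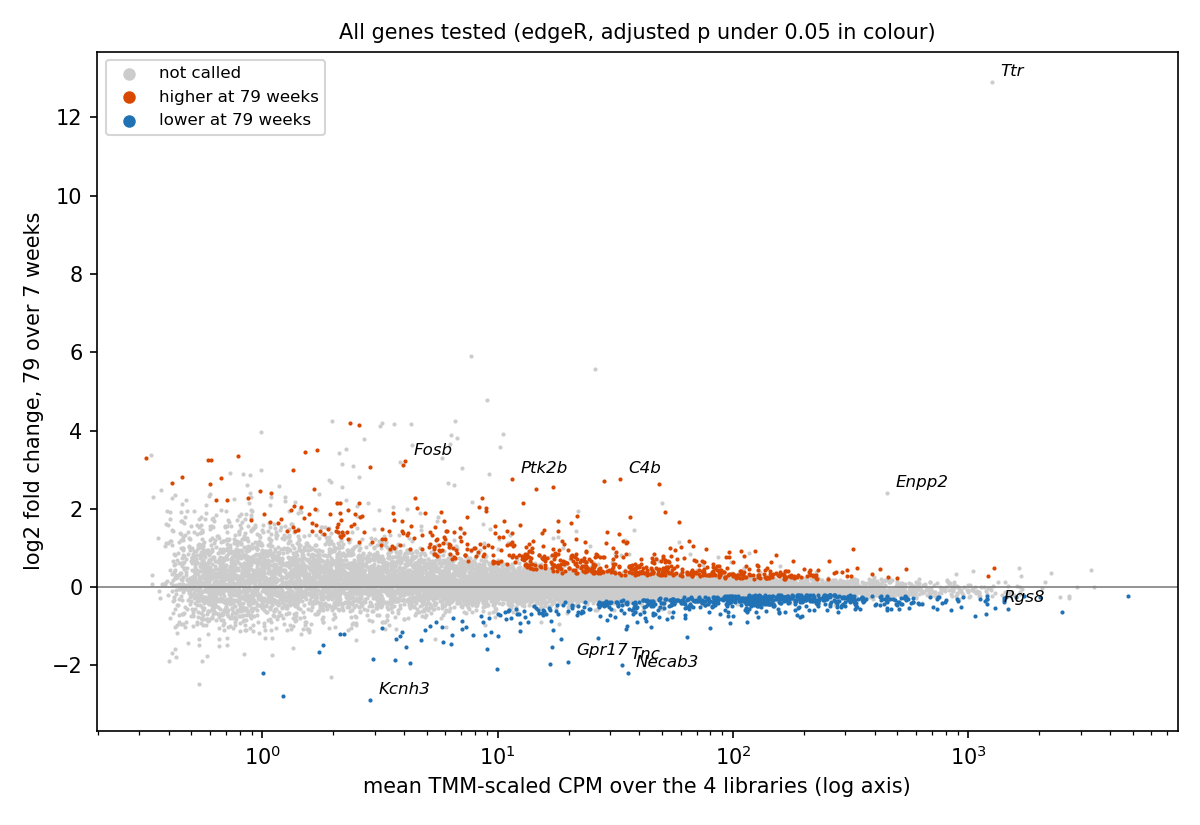
Log2 fold change at 79 over 7 weeks (vertical axis) against mean CPM over the 4 libraries (horizontal log axis) for the 15292 genes tested, each a point, with the 637 genes called higher in orange, the 715 called lower in blue and the rest in grey. Ttr and Enpp2 lie far above 0 without being called, with log2 fold changes of 12.90 and 2.41.

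The 10 largest rises among expressed genes were those of Xlr3b, Ostn, C3, Tekt1, Fosb, Cda, Tcap, Lmx1a, C4b and Ptk2b, with log2 fold changes from 4.19 for Xlr3b to 2.76 for Ptk2b. Complement C3 went from 0.26 ± 0.11 to 3.14 ± 0.20 CPM (log2 fold change 3.51, SE 0.39, adjusted p = 0.0053), and C4b from 8.44 ± 0.83 to 57.6 ± 12.9 CPM (2.77, SE 0.17, adjusted p = 0.00161). The 10 largest falls were those of Kcnh3, Dsc2, Neu2, Necab3, Gcnt1, Tnc, Pappa, Cpsf4l, Gpr17 and Mkrn3, with log2 fold changes from -2.88 for Kcnh3 to -1.86 for Mkrn3. Kcnh3, which encodes a voltage-gated potassium channel, went from 5.05 ± 1.75 to 0.67 ± 0.21 CPM (SE 0.38, adjusted p = 0.00903). Tnc, which encodes the matrix protein tenascin C, fell from 53.9 ± 0.57 to 13.5 ± 2.83 CPM (log2 fold change -1.999, SE 0.13, adjusted p = 0.00211). The smallest p-values belonged to Ptk2b, Tpbg, Gpr17, C4b and Tnc. Xlr3b, Ostn and Tekt1 differed by several fold between the 79-week libraries, and limma-voom did not call them (adjusted p = 0.16, 0.129 and 0.132). The log2 fold change of Xlr3b was 2.32 without 79-week replicate 2 and that of Ostn 2.69 without 79-week replicate 1, while without 7-week replicate 2 they were 5.10 and 5.22 (adjusted p = 0.173 and 0.133). Tekt1, a gene of motile cilia, was at 4.56 CPM in 79-week replicate 1, the library high in choroid plexus markers, and at 1.04 CPM in replicate 2. It was not called without 79-week replicate 1 (log2 fold change 2.05, adjusted p = 0.0697), and DESeq2 did not call Neu2 (adjusted p = 0.0688).

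Complement marks targets for uptake by phagocytes, and antigen presentation displays peptides to lymphocytes. Of 22 tested members of their list 9 rose, 0 fell and 13 were not called, and adjusted over the list alone 14 rose. C1qa and C1qc, chains of the complement initiator C1q, rose 2.33-fold and 2.13-fold, and Tap2, a peptide transporter of antigen presentation, rose 2.74-fold (log2 fold change 1.45, SE 0.14, adjusted p = 0.00379). The list was higher in camera (adjusted p = 2.83e-16), which was not so with an estimated correlation (adjusted p = 0.421 with an estimated correlation). Its median member stood 1.01 log2 units above the 7-week mean in 79-week replicate 1, the library high in choroid plexus markers. In 79-week replicate 2 it stood 0.66 above that mean.

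Interferon-stimulated genes rose in 10 of 27 tested members, with 0 lower and 17 not called, and adjusted over the list alone 17 rose. The list had a median log2 fold change of 1.08 (camera adjusted p = 6.77e-12, but adjusted p = 0.523 with an estimated correlation). Lgals3bp rose 6.55-fold, the transcription factor gene Irf7 4.81-fold, Mx2 3.63-fold and Ifi27 3.53-fold. Levels in 79-week replicate 1 exceeded those in replicate 2 for Lgals3bp, at 63.5 against 34.4 CPM, and Irf7, at 9.63 against 5.14 CPM. The median was 0.65 without 79-week replicate 1 and 1.66 without 7-week replicate 2, and the list stayed called in both fits (adjusted p = 9.7e-10 and 2.1e-15). The median member stood at 1.37 in 79-week replicate 1, the library high in choroid plexus markers, and at 0.63 in replicate 2. With robust dispersion estimates in edgeR, Lgals3bp and Ifi27 were not called (adjusted p = 0.0998 and 0.0575).

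Microglia, the resident macrophages of the brain, were covered by 2 lists. Of 22 general microglial markers 9 rose, 0 fell and 13 were not called. Adjusted over the list alone, 15 rose and 1 fell (median log2 fold change 0.64, camera adjusted p = 1.18e-09, adjusted p = 0.523 with an estimated correlation). The lysosomal protease gene Ctss rose 2.57-fold, from 18.4 ± 1.19 to 47.4 ± 8.97 CPM, and Laptm5 and Cx3cr1 rose 1.74-fold and 1.67-fold. Of 18 genes of activated microglia 8 rose, 0 fell and 10 were not called, and 17 rose when adjusted over the list alone. Their median log2 fold change was 1.06 (camera adjusted p = 1.04e-11, adjusted p = 0.421 with an estimated correlation). Lgals3 rose 3.51-fold, the lysozyme gene Lyz2 2.84-fold, Ctsz 1.71-fold and Cd9 1.39-fold. The median member of the activated list stood 0.86 and 0.89 log2 units above the 7-week mean in 79-week replicates 1 and 2.

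Reactive astrocyte genes were higher as a list, with 2 of 20 tested members called higher, 0 lower and 18 not called, and 3 higher when adjusted over the list alone. The astrocyte filament gene Gfap rose 1.58-fold, from 140 ± 10.7 to 221 ± 37.5 CPM, and Fbln5 rose 1.95-fold. The list's median log2 fold change was 0.41 (camera adjusted p = 0.00373, adjusted p = 0.523 with an estimated correlation), and 0.25 without 79-week replicate 1, the library high in choroid plexus markers. Gfap was not called with robust dispersion estimates (adjusted p = 0.0725).

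Immediate early genes, which neurons induce on activity, were higher in 5 of 17 tested members, with 0 lower and 12 not called. Adjusted over the list alone, 12 were higher and 1 lower (median log2 fold change 0.86, camera adjusted p = 4.64e-08, adjusted p = 0.523 with an estimated correlation). Fosb rose 9.25-fold, Fos 6.16-fold, Nr4a1 3.15-fold and Nr4a3 2.26-fold. The 79-week libraries differed, with Fos at 116.5 CPM in replicate 1 and 50.6 CPM in replicate 2, and the list's median was 0.35 without 79-week replicate 1, where the log2 fold change of Nr4a1 was 0.94 against 1.65 with all libraries. Without 7-week replicate 2 that of Fos was 3.31 (adjusted p = 0.0756). Fos, Nr4a1 and Nr4a3 were not called with robust dispersion estimates (adjusted p = 0.238, 0.306 and 0.0637). The list's median member stood 1.10 above the 7-week mean in 79-week replicate 1 and 0.36 in replicate 2, where choroid plexus markers stood at 4.21 and 0.47, meninges markers at 0.72 and -0.02 and ependymal markers at 0.97 and 0.13.

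Cytosolic ribosomal proteins build the ribosomes that make the proteins of the cell. Of 41 members 18 rose, 0 fell and 23 were not called, and 35 rose when adjusted over the list alone. The median log2 fold change was 0.25, and the median member stood 0.24 above the 7-week mean in each 79-week library. Camera gave an adjusted p of 1.03e-15 (adjusted p = 0.523 with an estimated correlation). Rpl8, Rps15 and Rps23 rose 1.24-fold, 1.27-fold and 1.26-fold.

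Heat shock proteins and chaperones moved both ways, with 2 of 22 members higher, 6 lower and 14 not called, and 3 higher and 11 lower when adjusted over the list alone. The co-chaperone gene Bag3 rose 1.80-fold. Hspa5, the main chaperone of the endoplasmic reticulum, fell by 0.47 on the log2 scale, Dnaja1 fell by 0.40 and Hspa4l fell by 0.29. The list was lower in camera (median -0.22, adjusted p = 0.00391, adjusted p = 0.565 with an estimated correlation). Genes of oxidative phosphorylation encoded in the nucleus had 0 higher, 1 lower and 42 not called of 43, and 0 were called when adjusted over the list alone. The member called was the cytochrome c gene Cycs, which fell by 0.35 on the log2 scale. The list's median was -0.07 (camera adjusted p = 0.0331, adjusted p = 0.523 with an estimated correlation). That call ended without 79-week replicate 1 (adjusted p = 0.123), without 7-week replicate 2 (0.0833), with library size scaling (0.169), with upper-quartile scaling (0.0509) and with a replicate block (0.0517). Circadian clock genes were called higher as a list (median 0.17, adjusted p = 0.0253, adjusted p = 0.543 with an estimated correlation), with 1 of 17 higher, 0 lower, 16 not called and 2 higher when adjusted over the list alone. The clock repressor gene Cry2 rose 1.21-fold and was not called without 79-week replicate 1 (adjusted p = 0.0569). The clock list was not called without 7-week replicate 1 (median 0.07, adjusted p = 0.264), 79-week replicate 1 (adjusted p = 0.0556) or 79-week replicate 2 (adjusted p = 0.0527).

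Markers of granule neurons, the most numerous cerebellar neurons, were lower at 79 weeks. Of 18 markers 7 fell, 1 rose and 10 were not called, and 11 fell and 1 rose when adjusted over the list alone. Gabra6, a receptor subunit particular to granule neurons, fell from 879 ± 13.5 to 591 ± 0.14 CPM (log2 fold change -0.57, SE 0.06, adjusted p = 0.00402). Etv1 fell by 0.54 and Cbln1 fell by 0.39 on the log2 scale, while Neurod2 rose 1.26-fold. The list's median was -0.23 (camera adjusted p = 2.37e-05, adjusted p = 0.523 with an estimated correlation). Of 22 markers of Purkinje cells, the output neurons of the cerebellar cortex, 10 fell, 0 rose and 12 were not called, and 11 fell when adjusted over the list alone. Rgs8 fell from 1539 ± 117.3 to 1065 ± 103.6 CPM, and Stk17b fell by 0.51 and Arhgef33 fell by 0.31 on the log2 scale. The Purkinje list's median was -0.16 (camera adjusted p = 3.3e-05, adjusted p = 0.421 with an estimated correlation), and -0.10 with library size scaling.

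Inhibitory interneuron markers were not called, with 0 of 19 higher or lower over all genes or adjusted over the list alone (camera adjusted p = 0.943). Their median was -0.01, like the direction in camera, while their mean was 0.02 and their median was 0.04 with library size scaling and without 79-week replicate 1, and 0.03 without 7-week replicate 2. The GABA-synthesis gene Gad1 stood at 575 ± 31.7 and 662 ± 37.1 CPM (adjusted p = 0.114). Gad1 was called higher with all libraries by DESeq2 (adjusted p = 0.0434) and without the low-count filter (adjusted p = 0.0424), and in edgeR without 79-week replicate 1 (adjusted p = 0.0306). Of 9 markers of unipolar brush cells, excitatory interneurons, 2 rose, 3 fell and 4 were not called. Lmx1a and Samd3 rose 7.99-fold and 6.87-fold, though the log2 fold change of Lmx1a was 4.20 without 7-week replicate 2 (adjusted p = 0.0727) and 2.45 without 7-week replicate 1 (adjusted p = 0.164), and Calb2 (chosen after its value was seen) fell by 0.45 on the log2 scale. Adjusted over the list alone, 3 rose and 4 fell. The unipolar brush list was not called (camera adjusted p = 0.639), with a median of -0.23 like the direction in camera and a mean of 0.49. Its median was 0.91 without 7-week replicate 2 and -0.03 without 79-week replicate 1.

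Synaptic receptors and vesicle proteins fell in 12 of 41 members, with 0 higher and 29 not called, and 23 fell when adjusted over the list alone. Homer1, a postsynaptic scaffold gene, fell by 0.68 on the log2 scale. Pclo, a scaffold of the presynaptic terminal, fell by 0.44, and the GABA receptor subunit gene Gabrb2 fell by 0.42. The list's median was -0.21 (camera adjusted p = 4.22e-09, adjusted p = 0.523 with an estimated correlation), and -0.24 and -0.19 in 79-week replicates 1 and 2 relative to the 7-week mean.

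Oligodendrocytes, which form myelin, were covered by 2 lists. Of 24 genes of myelinating oligodendrocytes 7 fell, 1 rose and 16 were not called, and 11 fell and 1 rose when adjusted over the list alone. The tight junction gene Cldn11 fell by 0.91 on the log2 scale, Ugt8a, which makes a myelin lipid, fell by 0.82, Mal fell by 0.75 and Tspan2 fell by 0.62. The myelin list's median was -0.32 (camera adjusted p = 4.6e-08, adjusted p = 0.536 with an estimated correlation). It was -0.15 without 79-week replicate 1 and -0.61 without 79-week replicate 2, and called in both (adjusted p = 0.00221 and 7.83e-22). Relative to the 7-week mean, its median member stood at -0.59 in 79-week replicate 1, the library high in choroid plexus markers, and at -0.15 in 79-week replicate 2. Of 15 genes of oligodendrocyte precursors 5 fell, 0 rose and 10 were not called, and 6 fell when adjusted over the list alone. Besides Gpr17, Neu4 fell by 0.99, Tnr fell by 0.47 and Fyn fell by 0.28 on the log2 scale. The precursor list's median was -0.21 (camera adjusted p = 3.04e-05, adjusted p = 0.523 with an estimated correlation), -0.05 without 7-week replicate 2 and -0.33 without 7-week replicate 1.

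Collagens and matrix proteins fell in 4 of 27 members, with 0 higher and 23 not called, and 6 fell when adjusted over the list alone. Besides Tnc, the fibrillar collagen gene Col3a1 fell by 1.44 on the log2 scale, the basement membrane gene Nid1 fell by 1.30 and Col18a1 fell by 0.24. The list's median was -0.22 (camera adjusted p = 8.72e-05, adjusted p = 0.523 with an estimated correlation). The median was -0.37 without 79-week replicate 1 and -0.06 without 79-week replicate 2, and the list stayed called in both fits (adjusted p = 2.2e-09 and 0.0333). Relative to the 7-week mean, the median member stood at -0.04 in 79-week replicate 1 and -0.36 in replicate 2, where meninges and fibroblast markers, of cells that make matrix, stood at 0.72 and -0.02 and choroid plexus markers at 4.21 and 0.47. Col18a1 was not called with library size scaling (adjusted p = 0.0688) or without 79-week replicate 2 (adjusted p = 0.0841).

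The enzymes that write and oxidise cytosine methylation bear on the marks the series measured in DNA. The methyltransferase gene Dnmt3a fell from 222 ± 10.4 to 172 ± 0.78 CPM (log2 fold change -0.37, SE 0.05, adjusted p = 0.0108). The dioxygenase genes Tet1 and Tet3, whose products turn methylcytosine into hydroxymethylcytosine, fell by 0.41 (SE 0.07, adjusted p = 0.0193) and fell by 0.36 (SE 0.06, adjusted p = 0.0188). Like all edgeR calls, those of Dnmt3a, Tet1 and Tet3 ended without 7-week replicate 1 (log2 fold changes -0.324, -0.457 and -0.341). Those of Tet1 and Tet3 also ended without 7-week replicate 2 (-0.358 and -0.378). Dnmt1 (log2 fold change -0.12, adjusted p = 0.241), Dnmt3b (0.07, adjusted p = 0.861) and Tet2 (0.31, adjusted p = 0.0763) were not called. Tet2 was called higher without 79-week replicate 2 (adjusted p = 0.00243) and with robust dispersion estimates (adjusted p = 0.0476), while its log2 fold change was 0.19 without 79-week replicate 1 (adjusted p = 0.241). That of Dnmt1 was -0.07 without 7-week replicate 1 and with library size scaling, and that of Dnmt3b ran from -0.03 without 79-week replicate 1 to 0.18 without 79-week replicate 2. Of the 20 tested genes of the methylation machinery 3 fell, 1 rose (Cxxc4, 1.25-fold) and 16 were not called, and adjusted over the list alone 4 fell and 2 rose. Cxxc4 was not called without 79-week replicate 1 (adjusted p = 0.0576) or 79-week replicate 2 (adjusted p = 0.073), with a replicate block (adjusted p = 0.0603) or by DESeq2 (adjusted p = 0.178). The list was not called (median -0.07, camera adjusted p = 0.221), and its median was -0.02 without 7-week replicate 2 and with library size scaling.

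**Figure D2:**
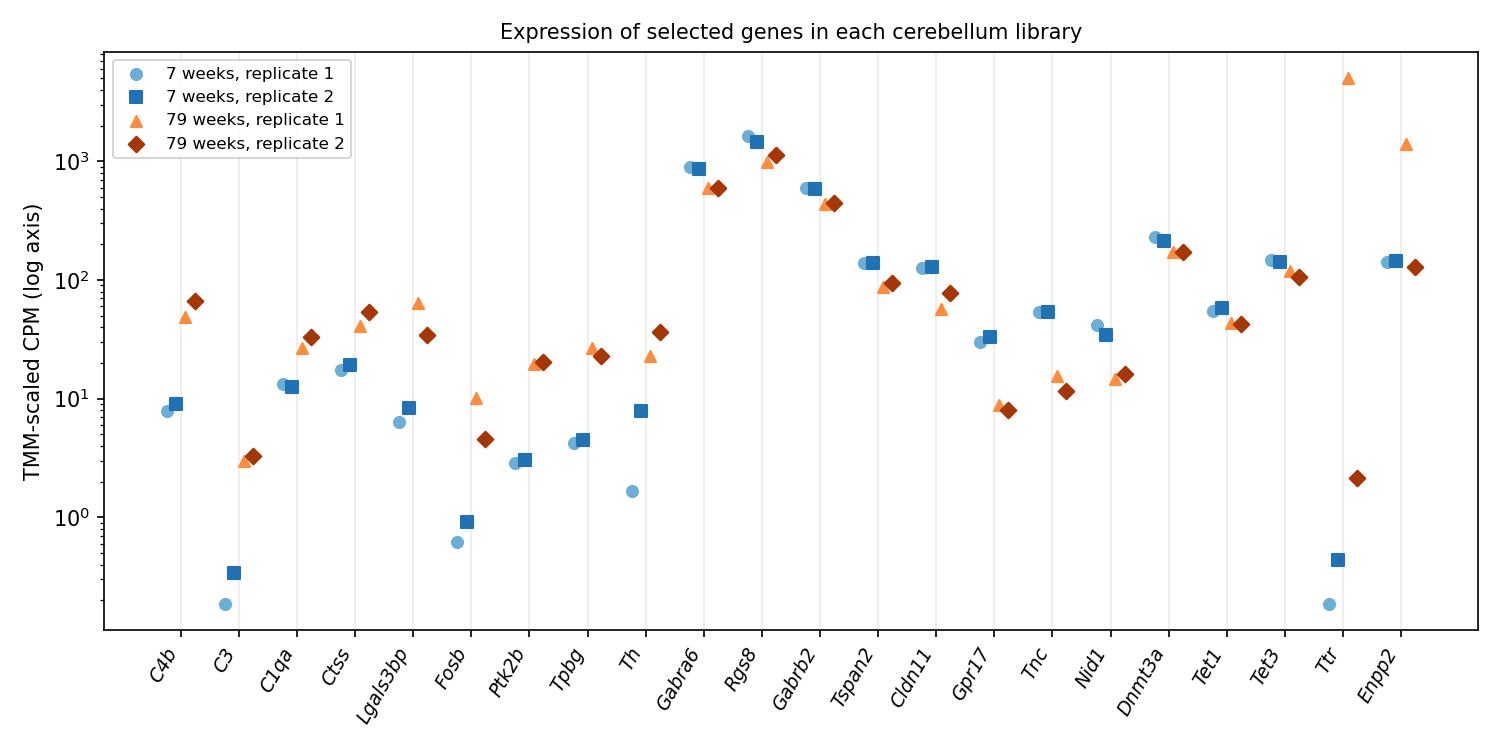
TMM-scaled CPM (vertical log axis) of 22 genes in the 4 cerebellum libraries, each symbol a library, with 7-week libraries in blue and 79-week libraries in orange and brown. C4b lies at 7.85 and 9.02 CPM at 7 weeks and at 48.5 and 66.7 CPM at 79 weeks, and Ttr reaches 5061 CPM in 79-week replicate 1 alone.

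Markers of choroid plexus, the tissue that projects into the ventricles and secretes cerebrospinal fluid, were high in 79-week replicate 1. Ttr, its most abundant secreted product, stood at 5061 CPM in that library, against 2.16 CPM in 79-week replicate 2 and 0.19 and 0.43 CPM at 7 weeks. Enpp2 stood at 1395 CPM there and at 129 CPM in 79-week replicate 2. Ttr was called higher without 79-week replicate 1 (log2 fold change 2.72, adjusted p = 0.00216), without 79-week replicate 2 (adjusted p = 8.5e-28), and with all libraries by DESeq2 (0.000164) and with a replicate block (0.000682). Enpp2 was called higher without 79-week replicate 2 (adjusted p = 4.56e-20) and without the low-count filter (adjusted p = 2.93e-227), and its log2 fold change was -0.15 without 79-week replicate 1. With all libraries limma-voom called neither Ttr nor Enpp2 (log2 fold changes 8.14 and 1.54, adjusted p = 0.842 and 0.359). A replicate block did not call Enpp2 (log2 fold change 1.59, adjusted p = 0.186). Of the 10 choroid plexus markers tested 0 were called over all genes, and all 10 were higher when adjusted over the list alone. The list was called higher (median log2 fold change 3.73, camera adjusted p = 0.000141, adjusted p = 0.543 with an estimated correlation), but not without 79-week replicate 1 (median 0.59, adjusted p = 0.0556), and its median was 6.55 without 79-week replicate 2. Ependymal genes, of the ciliated cells of the ventricle wall, were higher in 2 of 9 members, with 0 lower, 7 not called and 3 higher when adjusted over the list alone. The ciliary motor gene Dnah11 rose 2.01-fold, to 68.8 and 75.3 CPM in the 79-week libraries, and Foxj1 rose 2.96-fold, to 20.15 and 9.12 CPM, with a log2 fold change of 0.89 without 79-week replicate 1 against 1.57 with all libraries. The ependymal median was 1.01 (camera adjusted p = 3.04e-05, adjusted p = 0.523 with an estimated correlation) and 0.24 without 79-week replicate 1 (adjusted p = 0.00583). It was 2.63 without 79-week replicate 2, 1.70 without 7-week replicate 1, 1.87 without 7-week replicate 2 and 2.07 without the low-count filter. The filter was run anew or left out in these fits, for the choroid plexus list too. The tested members of both lists can therefore differ between fits. Markers of meninges and fibroblasts had 0 of 17 called over all genes or adjusted over the list alone. That list was called higher (median 0.48, adjusted p = 0.0105, adjusted p = 0.663 with an estimated correlation). It turned to -0.06 without 79-week replicate 1 (adjusted p = 0.88) and was not called without 7-week replicate 1 (median 0.22, adjusted p = 0.156), and its median was 0.73 without 79-week replicate 2. Ptgds and Igf2, its most abundant members, stood at 981 and 228.5 CPM in 79-week replicate 1 and at 731.5 and 72.9 CPM in replicate 2. Their log2 fold changes were -0.06 and -0.18 without 79-week replicate 1, and both were called higher without 79-week replicate 2 (adjusted p = 0.0127 and 6.07e-12).

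**Figure D3:**
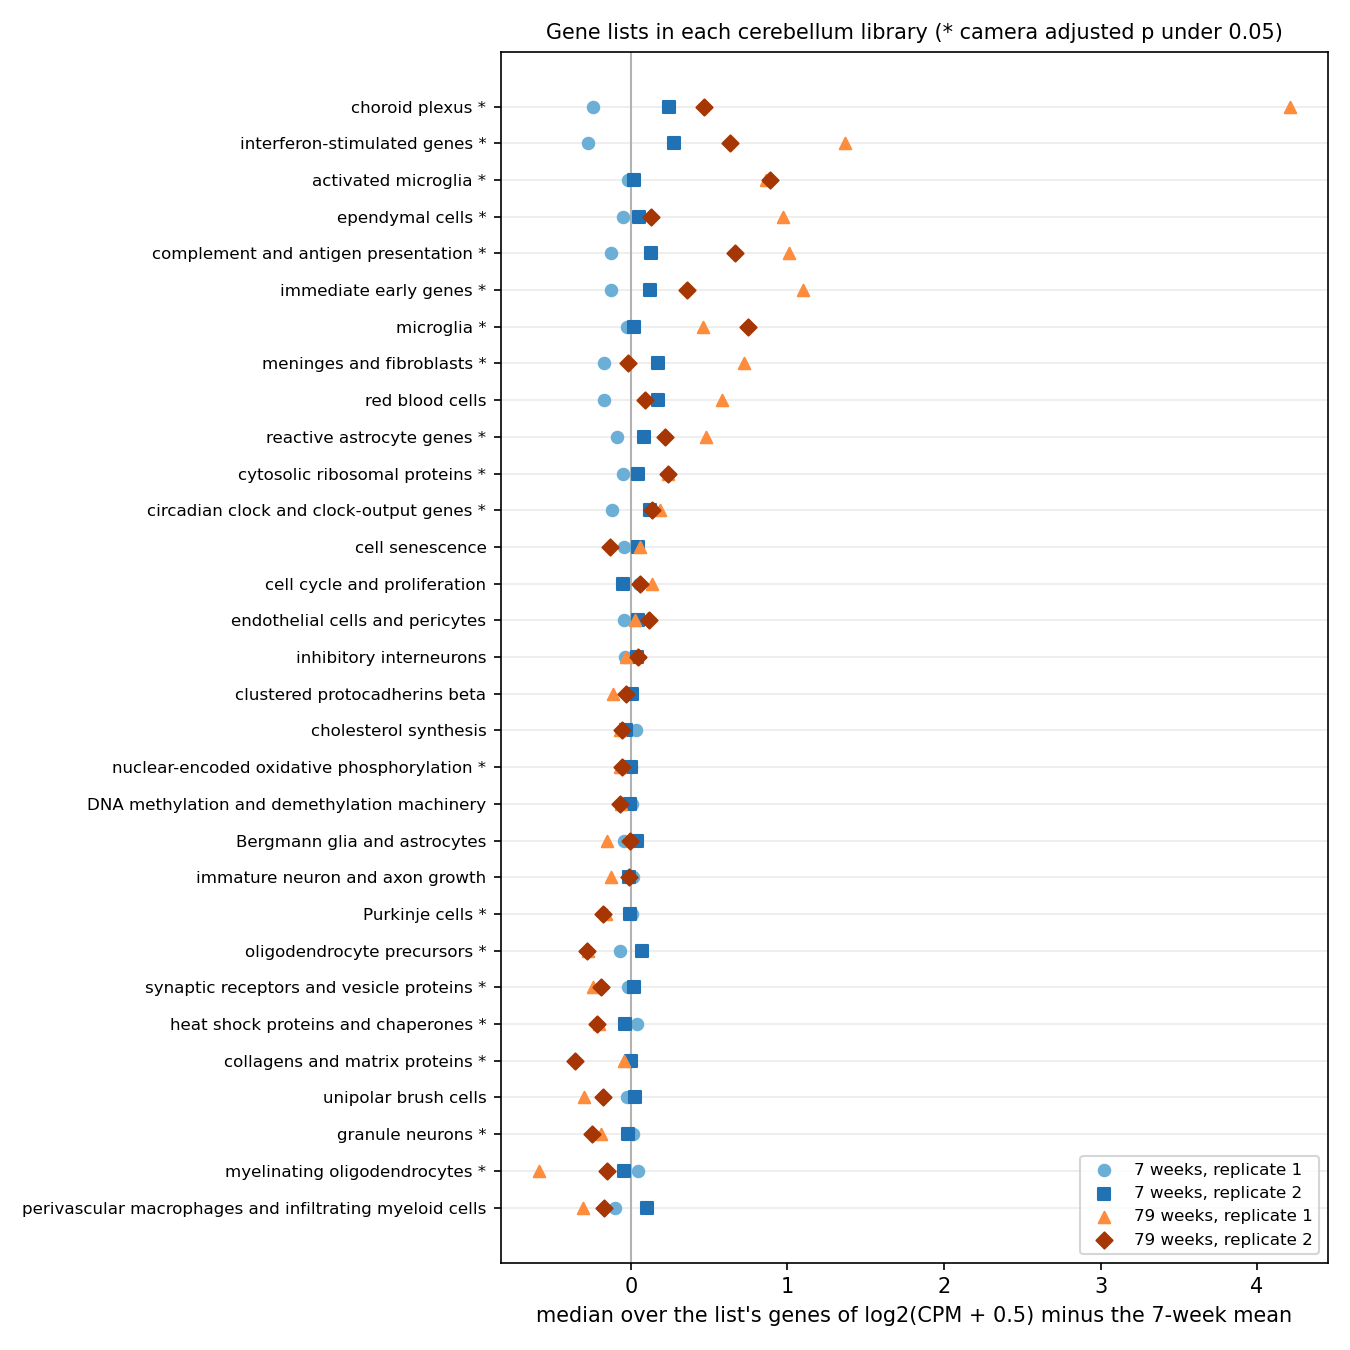
Median over each list's tested genes of log2(CPM + 0.5) minus the 7-week mean (horizontal axis), for the 31 lists tested (vertical axis), with a symbol per library and an asterisk where camera called the list. The choroid plexus list lies at 4.21 in 79-week replicate 1 and at 0.47 in 79-week replicate 2, while the activated microglia list lies at 0.86 and 0.89.

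The remaining tested lists were not called. Bergmann glia and astrocyte markers had 1 higher, 2 lower and 19 not called, the same counts when adjusted over the list alone (camera adjusted p = 0.435). Aldh1l1 rose 1.27-fold, Fabp7 fell by 0.87 and the glutamate transporter gene Slc1a3 fell by 0.25 on the log2 scale. That list was called lower without 79-week replicate 2 (median -0.16, adjusted p = 0.0333), and camera put it higher, uncalled, without 7-week replicate 2 or 79-week replicate 1 (adjusted p = 0.76 and 0.641). Slc1a3 was not called without 79-week replicate 1 (adjusted p = 0.0781). Cell cycle genes had 1 higher and 17 not called, with 2 higher when adjusted over the list alone (median 0.09, adjusted p = 0.475, but 0.02 without 7-week replicate 2, -0.03 without 79-week replicate 1 and 0.17 without 79-week replicate 2), and the replication gene Mcm6 rose 1.83-fold. Immature neuron and axon growth genes had 3 higher, 2 lower and 18 not called, with 3 higher and 5 lower when adjusted over the list alone (median -0.13, adjusted p = 0.221, but -0.06 without 79-week replicate 1). Among them Nnat and Stmn1 rose 1.32-fold and 1.23-fold, and Dpysl3 fell by 0.59 and Tubb2b fell by 0.32. Stmn1 was not called without 79-week replicate 2 (adjusted p = 0.117). In cholesterol synthesis 2 of 21 genes fell, among them Sqle, which encodes a rate-limiting enzyme and fell by 0.38, with 19 not called, and 1 higher and 2 lower when adjusted over the list alone. That list's adjusted p was 0.491, and Sqle was not called with library size scaling (adjusted p = 0.0719) or without 79-week replicate 2 (adjusted p = 0.0527). Senescence genes had 1 higher (Serpine2, 1.32-fold), 1 lower (the cell cycle inhibitor gene Cdkn1a, which fell by 0.56) and 9 not called, with 2 higher and 3 lower when adjusted over the list alone. The senescence list's median was 0.10 and its mean 0.05, while camera put it lower (adjusted p = 0.746). Without 79-week replicate 2 camera called it higher (adjusted p = 0.00513), and without 7-week replicate 2 put it higher without a call (adjusted p = 0.912). The median was 0.03 without 7-week replicate 1 and -0.13 without 79-week replicate 1. The medians of cholesterol synthesis and of clustered protocadherins beta were -0.03 and -0.02, and both turned to 0.03 with library size scaling and were -0.01 with upper-quartile scaling. Without 7-week replicate 1, 7-week replicate 2, 79-week replicate 1 and 79-week replicate 2 the cholesterol median was -0.01, -0.05, -0.06 and -0.08. That of protocadherins was -0.04 without 7-week replicate 2 or 79-week replicate 1 and -0.15 without 79-week replicate 2. Clustered protocadherins beta had Pcdhb14 higher, Pcdhb19 lower and 19 not called, the same when adjusted over the list alone (adjusted p = 0.647). Pcdhb19 was not called with library size scaling (adjusted p = 0.0508), with a replicate block (0.0552) or by DESeq2 (0.134).

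Among vessels and blood, Itm2a was the 1 called of 20 markers of endothelial cells and pericytes and fell by 0.41, with 19 not called and 1 lower when adjusted over the list alone (camera adjusted p = 0.639). Itm2a was not called without 79-week replicate 1 (adjusted p = 0.056), and the endothelial list, with a median of 0.09, was put lower by camera, uncalled, without 7-week replicate 1 or 79-week replicate 2 (adjusted p = 0.897 and 0.893). Red blood cell genes had 0 of 7 called, with 1 higher when adjusted over the list alone (adjusted p = 0.219). Hbb-bs stood at 20.3 ± 6.90 and 29.2 ± 0.70 CPM. Hbb-bs was called higher without 7-week replicate 2 (adjusted p = 0.0404) or 79-week replicate 2 (0.0345). That list was called higher without 7-week replicate 2 (adjusted p = 0.0144), and its median of 0.42 was 0.21 without 7-week replicate 1 and 0.09 without 79-week replicate 1. Perivascular macrophage and myeloid markers had 0 of 5 called over all genes or adjusted over the list alone (median -0.43, adjusted p = 0.312, but -0.71 without 7-week replicate 1 and -0.16 without 7-week replicate 2), with Stab1 at 11.4 ± 0.72 and 10.1 ± 0.10 CPM and Mrc1 at 3.30 ± 0.79 and 2.37 ± 0.24 CPM. The remaining 3 lists had fewer than 5 tested members. Of 4 tested brainstem and midbrain genes, Th, which encodes the rate-limiting enzyme of dopamine synthesis, rose 5.91-fold, from 1.68 and 7.91 CPM to 22.8 and 36.3 CPM, the neurofilament gene Nefh fell by 0.42, and 2 were not called. Their median was -0.15 and their mean 0.23. Without 7-week replicate 2, where at least 5 members were tested, the median was 1.54, camera called the list higher (adjusted p = 0.00658) and the log2 fold change of Th was 4.13 against 2.56 with all libraries and 1.90 without 7-week replicate 1 (adjusted p = 0.114). The median was -0.04 without 7-week replicate 1, 0.17 without 79-week replicate 1 (adjusted p = 0.0978) and -0.25 without 79-week replicate 2. The same 1 rose and 1 fell when adjusted over the list alone. Of 2 tested lymphocyte genes the immunoglobulin gene Ighm rose 1.96-fold and 1 was not called, as when adjusted over the list alone (median 0.79, but 2 without 79-week replicate 2). DESeq2 called neither Th (adjusted p = 0.0962) nor Ighm (adjusted p = 0.15). With a replicate block Ighm was not called either (adjusted p = 0.0662), nor was Th with robust dispersion estimates (adjusted p = 0.264). The 13 genes of mitochondrially encoded proteins had 0 reads and were not tested, and whether the mitochondrial genome was part of the alignment is not given, so their expression is not known here.

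Some other called genes named above lost their call with another test. DESeq2 did not call Nr4a1, Mcm6, Sqle or Itm2a (adjusted p = 0.0588, 0.0521, 0.0823 and 0.0729). Limma-voom did not call Nr4a1, Cry2, Stmn1, Sqle or Foxj1 (adjusted p = 0.0685, 0.0559, 0.0507, 0.0518 and 0.0994). Robust dispersion estimates ended the calls of Xlr3b, Ostn, Tekt1, Necab3, Pappa, Mal and Foxj1 (adjusted p = 0.216, 0.144, 0.088, 0.0715, 0.0815, 0.0657 and 0.157), and edgeR with legacy=FALSE those of Xlr3b and Tekt1 (adjusted p = 0.0547 and 0.0635). Upper-quartile scaling ended those of Sqle and Slc1a3 (adjusted p = 0.0509 and 0.0547), and library size scaling that of Slc1a3 (adjusted p = 0.0741). Without the low-count filter Tet2, Igf2 and Hbb-bs were called higher (adjusted p = 0.000905, 5.72e-36 and 6.6e-05).

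Over all lists, camera with a preset correlation called 19 of 31, 11 higher and 8 lower. With an estimated correlation it called 0 (3 at an unadjusted p under 0.05), and fry called 0 in 1 direction (8 at an unadjusted p under 0.05) and 18 for change in either direction. Levels of Xlr3b, C4b, Mx2, Ighm, Hbb-bs, Pcdhb14, Pcdhb19, Tubb2b and the ribosomal protein genes are uncertain, because reads shared with near-identical copies were not counted. Necab3 lies beside E2f1, which also fell (chosen after its value was seen, log2 fold change -1.83, adjusted p = 0.0177), and reads of neighbours cannot be told apart without the strand setting of the counting.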

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

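The tests in this part were all chosen after the results were seen, on lists fixed beforehand. Reads outside annotated genes and unaligned reads, which no comparison used, were more frequent at 79 weeks. Reads in no annotated gene made up 19.96% and 20.38% of the 79-week libraries (replicates 1 and 2), against 18.72% and 18.86% at 7 weeks. Unaligned reads made up 10.35% and 11.43% of the 79-week libraries, against 7.965% and 9.8% at 7 weeks. Age, RNA quality and library preparation were not told apart for these shares, and no biological explanation was tested.

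The first pattern was the level of choroid plexus markers in 79-week replicate 1. All 10 tested markers were more than 2-fold higher there than in 79-week replicate 2, led by Ttr at 5061 against 2.16 CPM and Enpp2 at 1395 against 129 CPM. The 7 markers of the list that had failed the low-count filter were also more than 2-fold higher in 79-week replicate 1 than in each other library (7 of 7). They had 88 to 687 counts there and 0 to 4 in each other library, so transcripts of these markers were high in that library. The filter drops genes high in 1 library alone but also genes low in all, so it did not fix this count. The test was, however, added after the list without the filter was seen. It therefore does not decide the cause, and choroid plexus tissue in that library stays open. An age change shared by both 79-week libraries was argued against as the whole cause, since the markers' median stood 4.21 log2 units above the 7-week mean in 79-week replicate 1 and 0.47 in replicate 2, where the 7-week libraries stood at -0.242 and 0.242, although 6 of 10 markers lay above both 7-week libraries in 79-week replicate 2 and Ttr was called higher without 79-week replicate 1 (log2 fold change 2.72). The tested markers held 0.69% of the gene counts of 79-week replicate 1 and 0.0154% of those of replicate 2, 3 of the 10 had at least 1 CPM in both 7-week libraries, and 0 belonged to another list. A smaller rise with age and a change in 79-week replicate 1 alone stay open.

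The second pattern was the rise of complement, interferon and activated microglia genes. Choroid plexus tissue as the whole cause was argued against, because their medians in 79-week replicate 2, which was low in choroid plexus markers, stood 0.663, 0.634 and 0.89 log2 units above the 7-week mean, where the 7-week libraries differed by a median of 0.353, 0.555 and 0.147. In that library 15 of 22, 20 of 27 and 17 of 18 members lay above both 7-week libraries. The argument is weakest for the interferon list, whose median member stood at -0.277 and 0.277 in the 7-week libraries. Whether activated microglia genes rose beyond a larger share of microglia cannot be told apart, since their median exceeded that of general microglial markers by 0.42 log2 units with a two-sided permutation p of 0.089 (adjusted over 3 such tests, 0.089) over 18 and 22 genes. Age stays among the open explanations and was not tested apart from other differences between the libraries.

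The third pattern was the fall of granule neuron and Purkinje cell markers. Dilution of all neurons by other tissue or cells would lower inhibitory interneuron markers alike, and the difference of medians from theirs was -0.22 log2 units for granule markers (two-sided permutation p = 0.00086, adjusted over 3 tests 0.00258) and -0.15 for Purkinje markers (permutation p = 0.00983, adjusted 0.0147). These differences exceed the median absolute deviation of the interneuron markers (0.127), the limit tried first, but not their SD (0.336), the limit used. Both limits were set after the values were seen, so neither decides, and dilution cannot be told apart. With each library left out the differences stayed negative, from -0.146 to -0.292 for granule markers and from -0.124 to -0.223 for Purkinje markers. Of the 19 interneuron markers, 17 lay above the granule median and 16 above the Purkinje median, while 9 had a positive and 10 a negative log2 fold change. The SD describes single markers and not a difference of medians, and the permutation treats genes as independent. Relative to the 7-week mean, granule and Purkinje medians stood at -0.191 and -0.156 in 79-week replicate 1 and at -0.251 and -0.179 in replicate 2. Their fall was thus not confined to replicate 1, the library high in choroid plexus markers. Fewer cells of these types, lower expression per cell and an effect of age stay open.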

How the results depend on the processing

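The crossed block and the DESeq2 fits without a library were chosen after the results were seen. Across alternatives, 1322 of the named-gene results and 338 of the list results kept direction and side of the threshold, 213 named-gene results fell short of it, 93 of these without 7-week replicate 1 and 69 without 7-week replicate 2, and no called gene changed direction in any setting. Scaling, filter and test left 1213 to 1746 genes called, apart from no low-count filter, with 3051 (1602 higher, 1449 lower). With a replicate block 1396 were called, 1215 of them shared. Crossed pairs gave 2014 (1010 higher, 1004 lower), so the same-numbered pairing gave fewer. Leaving out 1 library gave 0 to 2425 genes, 0 to 1360 higher and 0 to 1065 lower. The 0 came without 7-week replicate 1 in edgeR (2610 at an unadjusted p under 0.05), where DESeq2 called 243. DESeq2 called 430, 382 and 656 without 7-week replicate 2, 79-week replicate 1 and 79-week replicate 2. Without a 7-week library the spread comes from the 79-week pair alone. That pair differed more, with a chi-square of 18.2 per degree of freedom against 6.46 for the 7-week pair. The chi-square grows with counts, and choroid plexus genes weigh heavily in it, as Ttr (5061 against 2.16 CPM) and Enpp2 (1395 against 129 CPM). It is therefore not the spread of a typical gene. Correlations of log2 CPM were 0.9867 for the 79-week pair and 0.9916 for the 7-week pair. Simulated changes were called without 7-week replicate 1, but the simulation gave both ages the same dispersion. It therefore does not bear on the missing calls, and their cause was not tested. An estimated correlation or fry each gave 0 lists higher and 0 lower, against 11 and 8, with 3 lists at an unadjusted p under 0.05 for the estimated correlation and 8 for fry. A correlation estimated from 4 libraries missed a simulated shift too, of 0.3 log2 units in genes that varied independently. That does not show how it treats larger shifts or genes that vary together.

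Reversed list directions belonged to lists not called, apart from meninges, and for all of them the cause was not tested. The senescence median was 0.315 without the low-count filter and 0.0974 with a 1 CPM filter, and ranged from -0.13 to 0.106 over left-out libraries. Inhibitory interneurons had 0.0421 with library size scaling, -0.0112 with the replicate block and -0.055 to 0.0411 over left-out libraries. Over left-out libraries the median was -0.307 to 0.909 for unipolar brush cells, -0.16 to -0.00488 for Bergmann glia and astrocytes, -0.014 to 0.135 for endothelial cells and pericytes and -0.0593 to 0.732 for meninges and fibroblasts. Brainstem and midbrain genes, too few to test with all libraries, had -0.252 to 1.54. Among genes, none of them called, Enpp2 had -0.147 to 3.28 over left-out libraries, Ptgds -0.0627 to 0.355, Igf2 -0.18 to 1.46 and Dnmt3b -0.0343 to 0.176. Depth limited detection to 0.131 to 0.183 CPM per library, mitochondrial genes apart.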

Other observations

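The test in this part was chosen after the results were seen. Potassium channel genes (symbols beginning with Kcn) seemed frequent among the genes lower at 79 weeks. Of 73 tested, 18 were called lower and 2 higher, so 24.7% were lower against 4.73% of other genes with a symbol (two-sided Fisher's exact p = 7.53e-09, adjusted p = 7.9e-07 over 105 families of symbols sharing 3 letters). It was the only family of the 105 with more lower calls at an adjusted p under 0.05. Kcna1, Kcnd2, Kcnj12 and Kcnma1 fell by 0.57, fell by 0.56, fell by 0.59 and fell by 0.42 on the log2 scale, while Kcnc4 rose 1.95-fold and Kcnh2 rose 1.27-fold. Between 16 and 18 were lower under the scaling alternatives, 5 without 7-week replicate 2, 0 without 7-week replicate 1 (where edgeR called 0 genes in all), 19 without 79-week replicate 1 and 22 without 79-week replicate 2. The family was noticed in the same calls and the test treats genes as independent, so it does not decide whether chance gave this share. Other families had similar shares without passing, such as Cam with 25% of 20 and Hsp with 23.1% of 26 (adjusted p = 0.0723 and 0.0657). Neuronal lists also held many lower calls, in 12 of 41 synaptic, 7 of 18 granule neuron and 10 of 22 Purkinje cell genes. Inhibitory interneuron markers had 0 of 19. Kcn genes were not compared with neuronal genes alone, so a fall particular to potassium channels is not shown.

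Some genes were picked after their values were seen. Camk4, Camkk2, Adcy1, Cacna1e and Dlg2 fell by 0.74, fell by 0.73, fell by 0.64, fell by 0.56 and fell by 0.48 on the log2 scale. Nr4a2 rose 3.79-fold, the long noncoding RNA gene Neat1 1.89-fold, Itpr3 2.25-fold, Trank1 1.98-fold and Nr3c2 2.18-fold. Ccnd1 fell from 47.4 ± 1.02 to 22.5 ± 3.74 CPM. Clec7a, an activated microglia gene, rose from 0.29 ± 0.06 to 1.66 ± 0.52 CPM.

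Principal components of the 4 libraries carried 60.6%, 22.7% and 16.7% of the variance, the first separating the ages and the second the 79-week libraries. Counts of the 79-week libraries differed from each other by a chi-square of 18.2 per degree of freedom, against 6.46 for the 7-week libraries. Pairs of different age ran from 15.4, for replicate 2 of each age, to 27.7, for replicate 1 of each age. By the chi-square alone, replicate 2 at 79 weeks was closer to replicate 2 at 7 weeks than to the other 79-week library. Correlations of log2 CPM were nearly equal for these pairs, at 0.9872 and 0.9867. The chi-square grows with counts, so abundant genes such as Ttr, at 5061 and 2.16 CPM in the 79-week libraries, weigh heavily in it. Which of these libraries is closer is therefore not decided.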
